A study of Mus musculus with 6 samples.

How the data were processed

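The 6 libraries came from untreated AHA-11a cells, a mouse line that carries a human X chromosome. Per the labels' protocols, RNA was purified with DNase I treatment, and libraries were made with a KAPA mRNA HyperPrep kit, which selects polyadenylated RNA, or with the corresponding kit for total RNA that removes ribosomal RNA. Per the labels, 75-bp paired-end reads were quantified with Salmon 0.14.1 within nf-core/rnaseq 1.4.2 against mouse mm39 with the X chromosome of human hg38 appended. The release of the gene annotation and the strand setting are not given in the sources used here. The authors deposited estimated counts per gene, one column per library, which are not normalized and need not be whole. They also deposited TPM values, scaled to transcript length and to the sum of each library over mouse and human genes together. Salmon divides reads that match several transcripts by a statistical estimate, so values of genes with near-identical copies depend on that estimate, and reads from human genes on other chromosomes had no matching target.

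The tables held 56701 identifiers, of which 54309 were mouse and 2392 human. Mouse symbols, classes and coordinates came from GENCODE release M39 (GRCm39, the same build as mm39) by identifier without version, which matched 53700 mouse identifiers and left 609 unmatched. Unmatched mouse identifiers took 0.174% ± 0.0252 of counts in poly(A)-selected and 3.59% ± 0.348 in rRNA-depleted libraries (SD, n = 3 each). Nothing used here paired the human identifiers with symbols. The comparison of human with mouse Firre, the ratios of other human and mouse ortholog pairs and human gene symbols were therefore not analysed here, although they had been planned, and human genes are given by identifier, with at most 2 in each direction.

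For the comparison of library types, estimated counts were rounded to whole numbers, filtered with filterByExpr (minimum count 10, minimum total 15), scaled by the trimmed mean of M-values (TMM) and fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, library type as the only term, all 6 libraries). The p-values were adjusted by the Benjamini-Hochberg method over the 22660 mouse and human genes tested, with a threshold of 0.05. Each SE is the log2 change divided by the square root of the F statistic. A gene with 0 counts in one library type is given as a lower bound against 3 counts per library, and such floors cover counting error only. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 14 lists with at least 5 tested members, and again with an estimated correlation, with which 0 of the 10 calls held and 1 list had an unadjusted p under 0.05. Shares of counts were compared by an exact permutation test in R.

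The design, the gene lists, the rule for named genes and the alternatives other than those named below as chosen later were fixed before the data were examined. Under that rule the text could name Firre and Hprt, the 6 genes with the largest change in each direction among called genes with a mean count of at least 50, a proper symbol (not that of a pseudogene, clone or predicted gene) and no overlap between the library types, human genes by the same rule, and up to 4 members of each list with the largest absolute change. The lists held replication-dependent histones, small nucleolar and Cajal body RNAs, small structured RNAs, nuclear lncRNAs, host transcripts of small nucleolar RNAs, ribosomal proteins, mitochondrial messenger RNAs, nuclear oxidative phosphorylation genes, genes with long introns, zinc finger genes, immediate early genes, cell division genes, extracellular matrix genes, and markers of fibroblasts and of epithelial, blood, endothelial, neural and pluripotent cells. Copies and overlaps of named genes were found in the annotation and with BLAST+ 2.17.0.

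The replicate numbers were checked for pairing. Deviations of 12166 genes from the mean of their library type correlated between same-numbered libraries at 0.503, 0.862 and 0.676 for numbers 1, 2 and 3. Across numbers, poly(A)-selected replicate 1 correlated with rRNA-depleted replicate 3 at 0.505, and poly(A)-selected replicate 3 with rRNA-depleted replicate 1 at 0.647. The values thus set apart the libraries numbered 2 only. They cannot decide how numbers 1 and 3 match, because deviations from a mean cancel within a library type. A distinct replicate 2 in both types therefore makes all the others correlate. That the numbers pair all the libraries was an assumption, which the labels do not state. Values from a fit with the replicate number as a block stand beside a result where they change its call or move a count by over 1.5 times.

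Alternatives to the main analysis were DESeq2 1.42.0, scaling by library size alone, no filter on low counts, offsets for gene length recovered from counts and TPM, limma on log2(TPM + 1), TMM factors from mouse genes alone, and leaving out each library in turn. Chosen after the data were seen were fits without both libraries numbered 2, mouse X genes as the comparison for human X genes, the block and an estimated correlation for the mouse X genes, the human share of counts within same-numbered pairs, histone bounds without one library, Lars2 with each library left out or the block, mitochondrial messenger RNAs summed with their nuclear copies, and list tests on log2(TPM + 1) or with the block and an estimated correlation together. The edgeR procedure was tested on simulated counts of the same 22660 genes. It called 58% of 100 genes changed 2-fold and 93% of 100 genes changed 4-fold in the right direction. Of the unchanged genes it called 14 (0.0625%). In the simulation few genes changed, mostly in equal numbers up and down, with independent noise between libraries. In the data 15102 genes were called and changes of at least 2-fold were mostly upward. The rate of false calls in the simulation therefore need not hold for the data.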

Results

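RNA was measured in AHA-11a, a mouse and human somatic cell hybrid line (also distributed as GM10324) made of mouse cells that retain a human X chromosome and are grown with hypoxanthine, aminopterin and thymidine. RNA from untreated cells was sequenced in 2 ways. There were 3 poly(A)-selected libraries and 3 total RNA libraries depleted of ribosomal RNA, which the submitters describe as biological replicates, although nothing in the labels says which culture each library came from. The question given for the study is whether differences in abundance and localization between human and mouse Firre, a long non-coding RNA (lncRNA) transcribed from the X chromosome, lie in the sequences themselves. Estimated counts assigned to genes summed to between 61158458 and 66909350 in the poly(A)-selected libraries and between 33762941 and 36301954 in the rRNA-depleted libraries. One count was therefore worth between 0.0150 and 0.0164 CPM (counts scaled to the library total) in the first type and between 0.0276 and 0.0296 CPM in the second. Values for human Firre were not analysed here, because the identifiers of the human genes were not paired with symbols, so the between-species ratio is not reported.

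Mouse Firre was expressed in all 6 libraries. In the main fit on counts, which was unpaired, its level did not differ between the library types by more than the spread between replicates. The gene (ENSMUSG00000085396.8) is annotated as a lncRNA on the minus strand of chromosome X, from 49644621 to 49724249 in GRCm39, and no other tested gene overlaps it. Firre was at 29.5 ± 6.46 TPM (SD, n = 3) in poly(A)-selected RNA and at 17.3 ± 2.58 TPM (SD, n = 3) in rRNA-depleted RNA, from between 1357 and 3776 counts per library. On the scaled count level it was at 55.9 ± 11.7 CPM and 44.6 ± 9.27 CPM (SD, n = 3 each), a log2 change of −0.33 ± 0.196 (SE) in rRNA-depleted over poly(A)-selected RNA, with an adjusted p of 0.168 in edgeR. With the replicate number as a block the log2 change was −0.33 ± 0.064 (SE) and the adjusted p was 1.85e-04. In edgeR on all 6 libraries the call thus depended on whether the replicate number was in the fit. The values leave the match of numbers 1 and 3 undecided. Pairing was not needed for the call in every fit. Without both libraries numbered 2, an unpaired edgeR fit chosen after the data were seen gave −0.34 with an adjusted p of 6.9e-04. In limma on log2(TPM + 1) the log2 change was −0.72 with an adjusted p of 0.00897, and without replicate 2 of the poly(A)-selected libraries edgeR gave −0.49 with an adjusted p of 0.0288. Over the alternatives tried, the adjusted p ranged from 1.85e-04 to 0.608.

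Firre lay low among lncRNAs in its response to the library type. Of the 3569 other mouse lncRNAs tested, 236 (6.61%) had a lower log2 change than Firre, and the median lncRNA stood at 1.48. Among the 83 lncRNAs whose mean CPM was within 1 log2 unit of that of Firre, 12 (14.5%) had a lower log2 change, 45 were called higher in rRNA-depleted RNA, 10 were called lower, and the median was 0.46. By TPM, Firre ranked between 83 and 112 among the expressed mouse lncRNAs of the poly(A)-selected libraries and between 130 and 150 in the rRNA-depleted libraries. Mouse Hprt1 (ENSMUSG00000025630.9, chromosome X, 52076892 to 52111304), a purine salvage enzyme, fell from 26.3 ± 1.73 to 14.8 ± 1.16 CPM (SD, n = 3 each), a 1.78-fold lower level (log2 change −0.83 ± 0.114 SE, edgeR adjusted p = 2.94e-04).

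**Figure D1:**
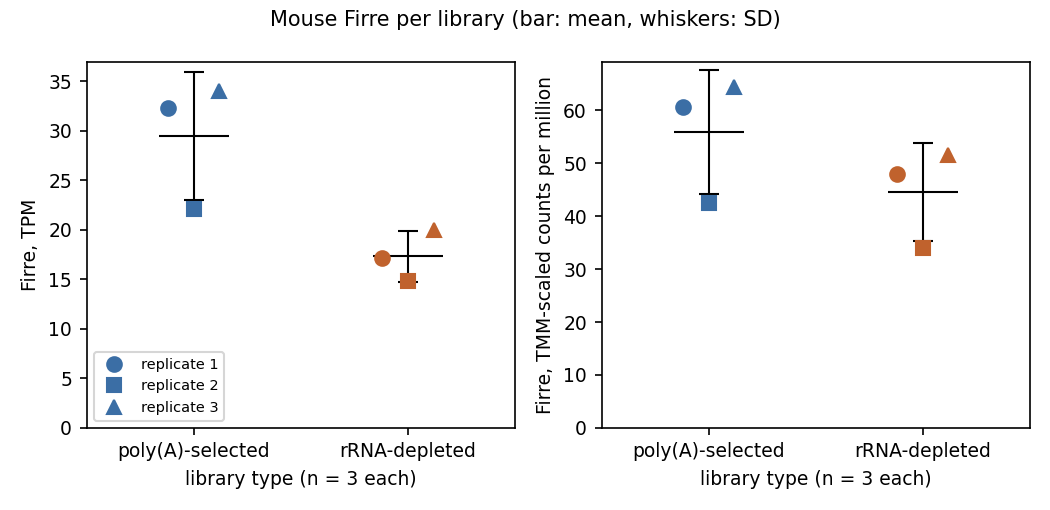
Firre in each library, as TPM (left axis panel) and as CPM scaled by the trimmed mean of M-values (right panel), by library type on the horizontal axis. Symbols are the 3 libraries of a type, with the shape giving the replicate number, bars are means and whiskers are SDs; the means are 29.5 and 17.3 TPM, and 55.9 and 44.6 CPM, and the libraries numbered 2 are the lowest of each type.

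Poly(A) selection and rRNA depletion gave different profiles across the transcriptome. Of 22660 genes tested, 15102 passed an adjusted p of 0.05 in edgeR, with 8806 higher and 6296 lower in rRNA-depleted RNA. At least 2-fold changes were mostly upward, with 7549 genes higher and 389 lower. The direction divided by gene class. Mouse protein-coding genes were more often lower, with 5738 lower and 2745 higher of 14115 and a median log2 change of −0.29. Mouse lncRNAs were mostly higher, with 2532 higher and 101 lower of 3570. Small nuclear RNAs had 78 of 94 genes higher and 0 lower, and small nucleolar RNAs had 134 of 184 higher and 2 lower. Processed pseudogenes had 874 of 1266 genes higher and 151 lower. Of the called genes 58.3% were higher in the main fit and 75.2% (9790 higher and 3236 lower) with scaling by library size alone, which moved the median of all genes from 0.037 to 0.25. In limma on log2(TPM + 1), which differs in test, unit and scaling together, 38.2% were higher (6686 higher and 10834 lower) and the median was −0.27. The values of the 3 libraries of one type did not overlap those of the other for 16032 genes (70.8%, where chance gives 10%).

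Transcripts that lack a poly(A) tail were among those with the largest increases in rRNA-depleted RNA. Among replication-dependent histone genes, which supply the histones packaged with newly made DNA, 55 of 59 tested members rose and 0 fell (56 and 0 adjusted over the list alone), with a median log2 change of 8.38, or 8.34 with members absent from poly(A)-selected RNA set at their lower bound. H3c13 on chromosome 3 (96175970 to 96176457) had 0 counts in the poly(A)-selected libraries and 67.9 ± 43.0 CPM (SD, n = 3) in the rRNA-depleted libraries, at least 1340-fold higher against a floor of 3 counts per library. H2bc18, its neighbour, was at least 936-fold higher and H2bc12 at least 100-fold higher. Replicate 2 of the rRNA-depleted libraries held most of these counts, and without it the bounds were 848-fold, 604-fold and 56.2-fold and the list's median was 7.69. H4c2 rose by a log2 change of 10.58 ± 0.657 (SE), or 9.97 without that library and 11.70 without replicate 2 of the poly(A)-selected libraries. The histone list passed the set test against all other genes (camera, adjusted p = 5.22e-24), but not when the correlation between its members was estimated (adjusted p = 0.414 with an estimated correlation). Histone cluster genes resemble each other closely in sequence, so the division of reads between single members is uncertain. H3c13 and H2bc18 also overlap Gm42743 on the same strand and Gm20628 on the opposite strand.

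Structured small RNAs without a poly(A) tail rose in all 9 tested cases (9 adjusted over the list alone), with a median log2 change of 8.43, or 6.54 with absent members at their bound (camera adjusted p = 3.16e-14; adjusted p = 0.163 with an estimated correlation). They included Rpph1, the RNA component of ribonuclease P, at 12.25 ± 0.272 (SE) from 0.0731 to 371 CPM, and Rn7s1, the RNA of the signal recognition particle, at 10.91 ± 0.391 (SE) from 8.08 to 15560 CPM. Rn7s6 was at least 33.1-fold higher and Rprl3 at least 23.9-fold higher. Rpph1 overlaps Ccnb1ip1 on the same strand and Parp2 on the opposite strand, and Rn7s6 overlaps Gm54521 on the same strand. Small nucleolar and Cajal body RNAs, guides of RNA modification, rose for 46 of 61 members and fell for 1 (46 and 1 adjusted over the list alone), with a median of 2.35 (camera adjusted p = 3.06e-10; adjusted p = 0.414 with an estimated correlation). Snord15b, Snord21 and Snord22 had 0 counts in poly(A)-selected RNA and were at least 212-fold, 205-fold and 91.0-fold higher, and Scarna10 rose by 10.36 ± 0.553 (SE), or 11.20 without replicate 2 of the poly(A)-selected libraries. These 4 RNAs lie inside Rps3, Rpl5, Snhg1 and Ncapd2 on the same strand, so reads of the unspliced host transcripts cannot be set apart from theirs in gene totals. The spliced host transcripts of such RNAs moved both ways, with 3 of 15 higher and 4 lower (2 and 3 adjusted over the list alone) and a median of −0.12 (camera adjusted p = 0.146). That median was 0.087 with scaling by library size alone, and on log2(TPM + 1) it was −0.76 with an adjusted p of 0.00419 (adjusted p = 0.65 on counts with an estimated correlation). Snhg14 stood at 0.78 ± 0.136 (SE), a call that was lost on log2(TPM + 1) (0.28, adjusted p = 0.0732), and Snhg3 at −0.73 ± 0.125 (SE).

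Nuclear lncRNAs were mostly higher in rRNA-depleted RNA. Of 14 tested members other than Firre, 11 rose and 1 fell (11 and 1 adjusted over the list alone; 11 and 2 with the replicate block), with a median log2 change of 1.05. The list passed camera with an adjusted p of 0.0176, but not with an estimated correlation (adjusted p = 0.49 with an estimated correlation) or on log2(TPM + 1) (adjusted p = 0.0884). Camera set this list against genes of every class and not against other lncRNAs. All tested mouse lncRNAs had a median of 1.48, with 2532 of 3570 higher. The median of the nuclear list lay below that value, so its rise was not particular to nuclear lncRNAs. Malat1, a lncRNA of nuclear speckles, rose from 2360 ± 640 to 20210 ± 5540 CPM (SD, n = 3 each), 8.56-fold. Kcnq1ot1, the antisense RNA of an imprinted domain, rose 5.96-fold from 155 CPM in poly(A)-selected RNA. Rian, of another imprinted region, rose 3.82-fold from a low level of 0.461 CPM. Neat1, the scaffold of paraspeckles, rose 3.67-fold on counts (log2 change 1.88 ± 0.193 SE), whereas its log2 change was −0.14 on log2(TPM + 1) and 0.31 with gene length offsets, neither of them past the threshold. Genes with very long introns had 11 of 21 members higher and 0 lower (11 and 0 adjusted over the list alone; median 0.35, camera adjusted p = 0.302). The set test of this list passed on log2(TPM + 1) (adjusted p = 0.00899) and without both libraries numbered 2 (0.0421), and not with an estimated correlation (adjusted p = 0.65 with an estimated correlation). Among them Nbea rose by 2.73 ± 0.275 (SE) from 0.532 CPM and Diaph2 by 1.56 ± 0.173 (SE) from 11.9 CPM. The list was set against genes of every class and not against mouse protein-coding genes alone, whose median was −0.29.

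Genes of the translation and respiration machinery were lower in rRNA-depleted RNA. Of 87 cytosolic ribosomal protein genes, 67 fell and 3 rose (69 and 4 adjusted over the list alone; 74 and 6 with the replicate block), with a median log2 change of −0.62 (camera adjusted p = 1.74e-13; adjusted p = 0.414 with an estimated correlation). Rpl22l1 fell from 177 ± 22.8 to 50.5 ± 3.88 CPM, Rpl10 from 291 ± 11.8 to 94.4 ± 5.03 CPM, and Rps27 from 96.4 ± 40.1 to 33.2 ± 7.05 CPM (SD, n = 3 each). Ribosomal protein genes have many processed pseudogenes, among which reads can be divided. Of the 87 tested, 84 are annotated as protein-coding. Rpl32l, the member with the largest change (−2.15 ± 0.683 SE), is annotated as a processed pseudogene. It had only 57 counts in the poly(A)-selected and 8 in the rRNA-depleted libraries. Its change was −3.46 without replicate 2 of the rRNA-depleted libraries. The call was lost without replicate 3 of that type (−1.99, edgeR adjusted p = 0.0734). Of 78 nuclear genes for oxidative phosphorylation subunits, 64 fell and 1 rose (65 and 2 adjusted over the list alone; 71 and 3 with the replicate block), with a median of −0.65 (camera adjusted p = 3.85e-12; adjusted p = 0.414 with an estimated correlation). The 1 member that rose over all genes is Cox7c-ps1, annotated as a processed pseudogene, and 77 of the 78 are annotated as protein-coding. Atp5me and Atp5f1e, small subunits of ATP synthase, fell 2.36-fold and 2.31-fold, and Ndufa4, a respiratory chain subunit, fell 2.21-fold. The share of the mitochondrial genome was taken without reads assigned to its nuclear copies. Its RNAs took 6.41% ± 0.919 of counts in poly(A)-selected and 2.89% ± 0.419 in rRNA-depleted libraries (SD, n = 3 each). Of its 13 messenger RNAs, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of −1.18 (camera adjusted p = 1.39e-05; adjusted p = 0.414 with an estimated correlation).

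Single mitochondrial values, and the size of the fall in the mitochondrial share, were uncertain where nuclear copies share the sequence. The change of mt-Co3, a cytochrome c oxidase subunit, was −3.76 ± 0.558 (SE) as counted (−4.43 without replicate 3 of the rRNA-depleted libraries), and Gm28437 on chromosome 1 (24652270 to 24653052) matches its transcript at 100% identity over 783 bases. Summed with that copy, mt-Co3 stood at −1.22 ± 0.230 (SE). Likewise mt-Co2 moved from −2.27 ± 0.187 (SE) to −0.997 ± 0.208 (SE) when summed with its copies, and mt-Nd3, the member that rose at 0.35 ± 0.132 (SE), stood at −0.70 ± 0.153 (SE) when summed with Gm28438. With copies summed, an alternative chosen after the data were seen, 12 of the 13 messenger RNAs fell and 0 rose, with a median of −1.12.

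The rule for named genes leaves out symbols of pseudogenes, clones and predicted genes, and 28 genes so left out, 21 of them pseudogenes, were called with larger decreases than mt-Co3. One of them is Atp6-ps, a copy of mt-Atp6 named here after its values were seen. It had 30032 counts in the poly(A)-selected libraries and 0 in the rRNA-depleted libraries, at least 2110-fold lower. Atp6-ps matches mt-Atp6 at 100% identity over 678 bases, so its counts depend on how shared reads were divided. The bound is therefore no bound on a change in its level. Among the genes the rule gave, Or51v14 and Or4k5, olfactory receptor genes, fell by 3.64 ± 0.126 and 2.66 ± 0.392 on the log2 scale (SE), from 51.2 to 4.10 CPM and from 3.57 to 0.560 CPM, and Or4k5 stood at −3.26 without replicate 3 of the rRNA-depleted libraries. Pecam1, an adhesion molecule of endothelial cells, fell from 44.1 ± 9.28 to 8.71 ± 0.621 CPM (SD, n = 3 each). The ribosomal RNAs that the depletion targets were also lower. The mitochondrial mt-Rnr2 fell by 2.66 ± 0.639 (SE), and stood at −3.96 without replicate 1 of the rRNA-depleted libraries. The cytoplasmic Rn18s-rs5 fell by 2.44 ± 0.848 (SE, edgeR adjusted p = 0.0312), a call that was lost without replicate 1 (adjusted p = 0.0683) or replicate 2 (0.0536) of the poly(A)-selected libraries or without replicate 2 of the rRNA-depleted libraries (0.0611). Its change was −4.31 without replicate 1 of the rRNA-depleted libraries (edgeR adjusted p = 1.86e-04) and −3.30 with the replicate block (adjusted p = 7.53e-07). Genes annotated as ribosomal RNA took 0.396% of counts in replicate 1 of the rRNA-depleted libraries, against 0.0654% and 0.0438% in the other two.

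**Figure D2:**
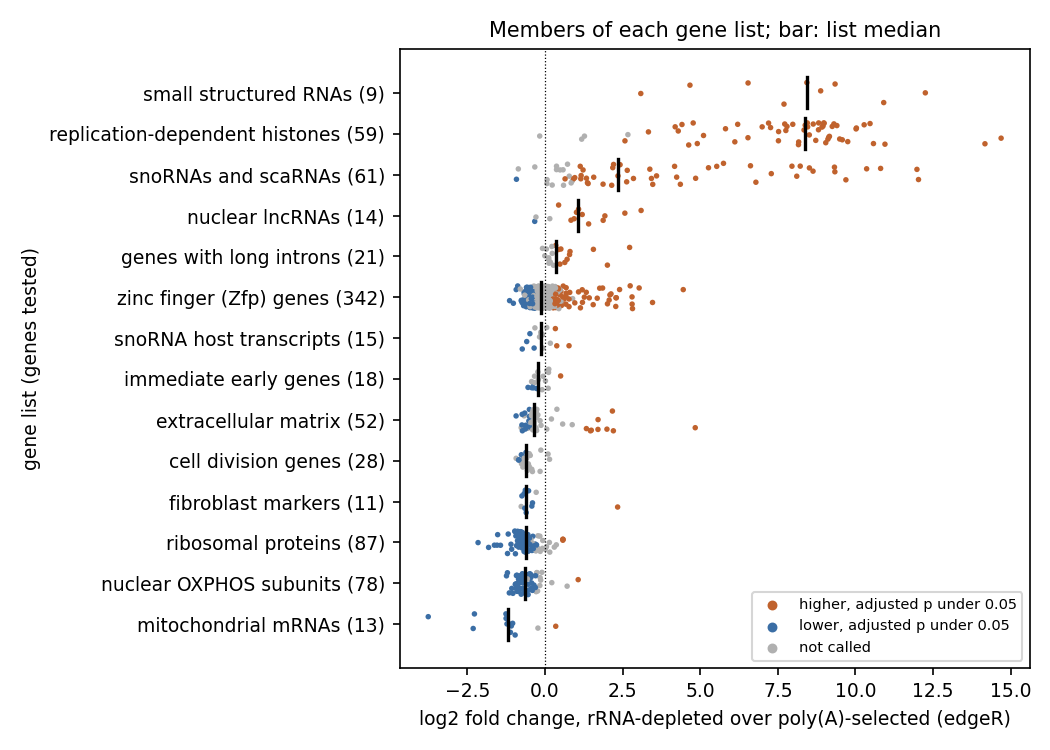
Log2 fold change in rRNA-depleted over poly(A)-selected RNA (horizontal axis, edgeR) for the tested members of each gene list (vertical axis, number tested in parentheses), 1 point per gene. Orange and blue points are higher and lower at an adjusted p under 0.05, grey points were not called, and black bars are list medians, which run from −1.18 for mitochondrial messenger RNAs to 8.43 for small structured RNAs; fitted values of genes with 0 counts in one library type are no measure of their size, and the zinc finger median turns from −0.11 to 0.096 with scaling by library size alone.

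Cell division genes and fibroblast markers were lower in rRNA-depleted RNA as lists, and few single cell division genes passed the unpaired test. Camera set both lists against genes of every class, while mouse protein-coding genes alone had a median of −0.29. Neither list was tested against other messenger RNAs, so a decrease particular to them was not shown. For 28 cell division genes the median log2 change was −0.60, or −0.15 without replicate 2 of the poly(A)-selected and −1.03 without replicate 2 of the rRNA-depleted libraries. Of them 5 fell, with 0 adjusted over the list alone in either direction by edgeR, where 6 had an unadjusted p under 0.05. DESeq2 called 10 members, and 6 adjusted over the list alone. With the replicate block 24 fell and 1 rose (camera adjusted p = 0.00794; 3.54e-06 with the block; adjusted p = 0.65 with an estimated correlation; 0.0567 without replicate 2 of the poly(A)-selected libraries). Ccnb2, a mitotic cyclin, fell by 0.83 ± 0.212 (SE) on the log2 scale, from 46.3 to 26.0 CPM, and Pcna, the sliding clamp of DNA replication, stood at −0.93 ± 0.367 (SE; edgeR adjusted p = 0.051, 9.68e-10 with the block, and under 0.05 in 9 other alternatives). Of 11 fibroblast markers 8 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of −0.60 (camera adjusted p = 0.0309; adjusted p = 0.49 with an estimated correlation; 0.0532 without replicate 1 of the poly(A)-selected libraries; 0.050 on log2(TPM + 1)). Sparc and Lgals1 fell 1.67-fold and 1.59-fold from 951 and 1315 CPM, and Thy1, near 0.244 CPM in poly(A)-selected RNA, rose by 2.34 ± 0.307 (SE). Both lists differed between libraries of one type. Relative to the mean of the library type, the median cell division gene stood at 0.61 in poly(A)-selected and 0.53 in rRNA-depleted replicate 2 and between −0.33 and −0.28 in the other 4 libraries, and the median fibroblast marker at −0.23 and −0.20 in both libraries numbered 2. Without those 2 libraries 17865 genes were called, and the cell division and fibroblast lists passed with adjusted p of 6.34e-06 and 0.0102.

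**Figure D3:**
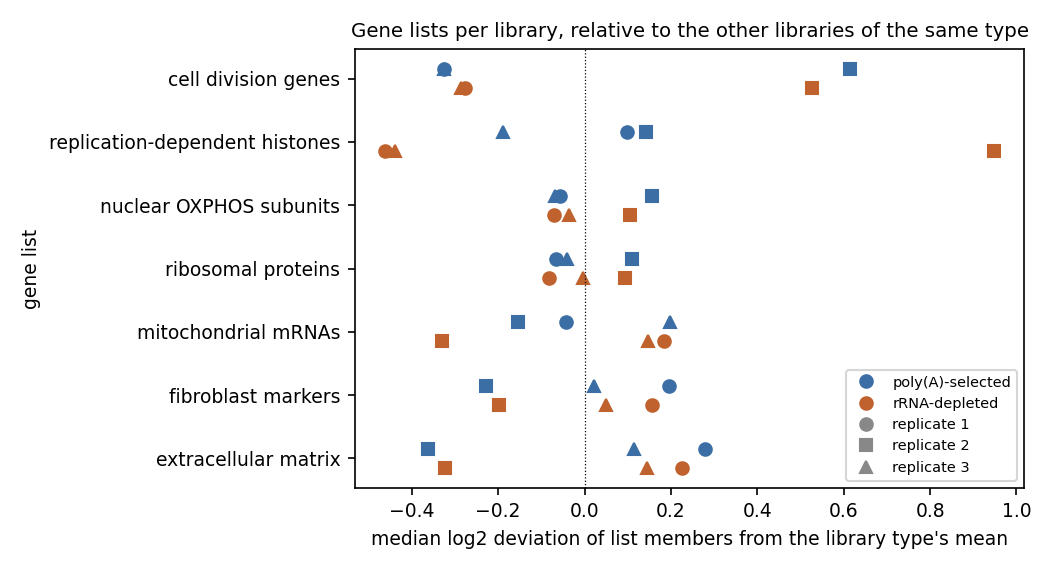
Median deviation of the members of 7 gene lists (vertical axis) from the mean of the library type (horizontal axis, log2 CPM), 1 symbol per library. Color gives the library type and shape the replicate number; both libraries numbered 2 are the highest of their type for cell division genes (0.61 and 0.53) and the lowest for extracellular matrix genes (−0.36 and −0.32).

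Extracellular matrix genes moved both ways, with 9 of 52 higher and 11 lower (9 and 6 adjusted over the list alone), and 11 higher and 32 lower with the replicate block. Their median was −0.35, their mean was 0.070 and camera pointed down (adjusted p = 0.0666; 0.0116 with the block; adjusted p = 0.692 with an estimated correlation, and 0.371 with both). Leaving out replicate 2 of the poly(A)-selected libraries, or replicate 1 or 3 of the rRNA-depleted libraries, gave 0.00644, 0.0153 and 0.026, library size alone gave 0.035 and leaving out both libraries numbered 2 gave 0.0102. The members that rose most were collagens of low level in poly(A)-selected RNA. Col10a1 rose by 4.84 ± 0.227 (SE) from 0.146 CPM, and it overlaps Nt5dc1 on the opposite strand, while Col4a4 rose by 2.21 ± 0.242 (SE) and overlaps Col4a3. Among 342 zinc finger genes 59 rose and 79 fell (50 and 66 adjusted over the list alone; 81 and 126 with the block). That list's median was −0.11 and its mean was 0.051. Camera pointed down for the zinc finger genes with an adjusted p of 0.0095. That call was lost with the block (0.114), without both libraries numbered 2 (0.142) and with an estimated correlation (adjusted p = 0.65 with an estimated correlation). Camera sets a list against genes of every class, while mouse protein-coding genes alone had a median of −0.29. The zinc finger and immediate early medians lay above that value and the extracellular matrix median lay close to it. Pointing down therefore does not set these lists below other messenger RNAs. Zfp750 rose by 4.46 ± 0.303 (SE) from 0.123 CPM in poly(A)-selected RNA and overlaps Tbcd on the opposite strand. Zfp457 rose by 3.04 ± 0.147 (SE) from 1.395 CPM. Of 18 immediate early response genes 5 fell and 1 rose (4 and 1 adjusted over the list alone; 8 and 1 with the block; median −0.22, camera adjusted p = 0.0755). The set test of this list passed without replicate 2 of the poly(A)-selected libraries (0.0388) and without replicate 1 or 3 of the rRNA-depleted libraries (0.0355 and 0.040), and on log2(TPM + 1) (0.00419, median −0.70), and not with an estimated correlation (adjusted p = 0.65 with an estimated correlation). Klf4, a transcription factor, stood at −0.54 ± 0.135 (SE), a call that was lost with library size alone (−0.33, adjusted p = 0.0578). Zfp36, an mRNA decay factor, stood at 0.51 ± 0.120 (SE) on counts, at −0.28 on log2(TPM + 1) and at 0.14 with gene length offsets, neither of the latter past the threshold.

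Markers of other cell types were sparse. Of the epithelial, blood, endothelial, neural and pluripotent marker lists, 2, 3, 3, 3 and 1 members were tested, too few for a set test. In each of the first 3 lists 1 member rose and 1 fell, over all genes and adjusted over the list alone, and none did in the last 2 by edgeR (adjusted p from 0.233 to 0.936). Single calls changed with the setting. Gfap, of astrocytes, moved from −0.81 to −1.84 without replicate 3 of the rRNA-depleted libraries (edgeR adjusted p = 0.0223). Mbp, of myelin, passed with gene length offsets (−0.49, adjusted p = 0.00753) and on log2(TPM + 1) (−0.82, adjusted p = 6.22e-04), and Nanog without both libraries numbered 2 (0.49, adjusted p = 0.0303). The epithelial Krt19 lost its call with library size alone and without replicate 3 of the poly(A)-selected or replicate 1 of the rRNA-depleted libraries (adjusted p = 0.0886, 0.0695 and 0.0651). Lyz2, of macrophages, passed on log2(TPM + 1) (−0.29, adjusted p = 0.00901), and the endothelial Vwf with the block (0.26, adjusted p = 0.0128) and with gene length offsets (0.76, adjusted p = 0.0149). Beside Pecam1, the endothelial Tie1 rose by 1.62 ± 0.271 (SE) from 0.409 CPM, a call that was lost on log2(TPM + 1) (0.11, adjusted p = 0.108), and the macrophage gene Cd68 fell from 49.9 ± 10.7 to 29.2 ± 4.88 CPM (SD, n = 3 each).

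The share of counts taken by genes of the human X chromosome was slightly lower in the rRNA-depleted library of each of the 3 same-numbered pairs. It was 0.928% ± 0.0548 in poly(A)-selected and 0.899% ± 0.0471 in rRNA-depleted libraries (SD, n = 3 each), a difference of −0.029 percentage points (exact two-sided permutation p = 0.5, where 0.1 is the smallest p that 3 against 3 libraries allow). Within the pairs, whose match is assumed for numbers 1 and 3, the difference was −0.029 ± 0.0158 (SD, n = 3 pairs). The exact two-sided sign-flip permutation p was 0.25, the smallest that 3 pairs allow, so neither design could reach 0.05. As a share of TPM it was 0.844% ± 0.0488 and 0.496% ± 0.0412. TPM values are scaled to the sum of each library, in which Rn7s1 alone held between 105100 and 123100 TPM with rRNA depletion. Relative to mouse X genes, the TPM of human X genes was 0.433 ± 0.0307 in poly(A)-selected and 0.562 ± 0.0378 in rRNA-depleted libraries (SD, n = 3 each). The lower TPM share was therefore not particular to human X genes. At least 10 counts were found for 649 ± 7 human genes in poly(A)-selected and 731 ± 12.5 in rRNA-depleted libraries, of 2392 identifiers, 952 of which had no counts in any of the 6 libraries. Of 728 human genes tested, 239 were higher and 205 lower in rRNA-depleted RNA, with a median log2 change of −0.061. As a set they did not pass the test against all mouse genes (camera, adjusted p = 0.147 over 3 tests of X-linked sets), nor with an estimated correlation (unadjusted p of 0.708). Among the human genes that the naming rule gave, ENSG00000201592.1 and ENSG00000231566.2 rose by 4.75 ± 0.259 and 3.81 ± 0.188 (SE), and ENSG00000130032.17 and ENSG00000101888.12 fell by 3.60 ± 0.280 and 1.38 ± 0.228 (SE).

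Mouse genes of the X chromosome were lower in rRNA-depleted RNA than all other genes tested (camera, adjusted p = 0.0039). Of 532 mouse X genes 232 were lower and 154 higher, with a median of −0.32. Mouse protein-coding genes as a whole had a median of −0.29, and no test was made within a gene class. A decrease particular to the X chromosome thus cannot be told apart from a difference in gene classes. The call of the mouse X genes was lost with an estimated correlation (unadjusted p of 0.214). It was kept with the replicate block (unadjusted p of 0.00111), both tried after the data were seen. Their share of counts was 2.28% ± 0.0634 in poly(A)-selected and 1.82% ± 0.0254 in rRNA-depleted libraries (SD, n = 3 each). Set against the mouse X genes directly, an alternative chosen after the data were seen, the human X genes had a median log2 change that was higher by 0.26, which did not pass the threshold (camera, adjusted p = 0.0808; unadjusted p of 0.597 with an estimated correlation). Counts of human X genes were 0.408 ± 0.0340 of those of mouse X genes in poly(A)-selected and 0.495 ± 0.0326 in rRNA-depleted libraries (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible).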

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

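The comparisons without both libraries numbered 2, against mouse X genes, within pairs for the human share, and of lists on log2(TPM + 1) or with block and estimated correlation together were chosen after the results were seen. The number of genes called ranged from 13026 to 18119 over the alternatives, within 1.5 times the 15102 reported, and 13574 to 16172 with 1 library left out. The count of genes lower in rRNA-depleted RNA was 3236 with scaling by library size alone and 10834 on log2(TPM + 1), against 6296. Scaling by library size alone moved the median of all genes to 0.25, and log2(TPM + 1) differs in test, unit and scaling together, so no single cause is given. Firre stayed lower throughout, and passed the threshold at −0.72 on log2(TPM + 1), −0.33 with the replicate block and −0.34 without both libraries numbered 2. With 1 library left out it ranged from −0.49 (without poly(A) replicate 2, past the threshold) to −0.18. Relative to the median of all genes Firre stood at −0.36, and at −0.37 with scaling by library size alone and −0.44 on log2(TPM + 1), with a range over all settings from −0.68 (without the low-count filter) to −0.29 (without poly(A) replicate 3). The difference between human X and mouse genes reversed to 0.13 without the low-count filter and to 0.26 against mouse X genes, without passing the threshold. The mouse X genes, with a median of −0.32, lost their call with an estimated correlation and kept it with the block, both chosen later. They were not tested against other genes of the same class. With an estimated correlation 0 of the 10 list calls held, with or without the replicate block. The share of human genes differed by −0.348 percentage points as TPM, against −0.029 as counts. The TPM of human X genes relative to mouse X genes rose from 0.433 to 0.562. Neat1 turned to −0.14 and Zfp36 to −0.28 on log2(TPM + 1). Where not stated, the cause was not tested. Over single genes and single lists, 1144 values stayed on their side of the threshold. Of them 14, medians of 2 lists and 12 values of uncalled genes, changed sign. Another 43 lost the call and 41 gained it. The 43 include the 10 list calls lost with an estimated correlation. The block changed no other call of a list or named gene than those given with the results, apart from Ier3, Col1a1 and Vwf, which it called, and with Vwf 2 endothelial markers rose. It moved no other count of a list by over 1.5 times. Human Firre and ortholog pairs were not analysed here under any setting. Of the 10 splits of the 6 libraries into equal groups, 1, the real one, called as many as 15102 genes. The highest of the others was 0 genes by edgeR at an adjusted p of 0.05 (4 to 631 at an unadjusted p), also for the 3 others that part all same-numbered pairs, but 10 splits are too few for a share under 0.05.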

Other observations

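The libraries numbered 2 stood apart in both library types, among others by genes of proliferation and of the matrix. With library type as a covariate, replicate number had an adjusted p under 0.05 in edgeR for 5354 of 22660 genes, an examination chosen after the data were seen. All 28 cell division genes were among them. Mcm2, a subunit of the replicative helicase, deviated by 1.02 in the libraries numbered 2, Pcna by 0.71 and Top2a, a topoisomerase of mitotic chromosomes, by 0.49, all chosen after their values were seen. Replication-dependent histone genes deviated by 0.95 in rRNA-depleted replicate 2 and by 0.14 in poly(A)-selected replicate 2. Of 52 extracellular matrix genes 34 passed, with medians of −0.36 and −0.32 in the libraries numbered 2. Col1a1 and Fn1, both abundant matrix proteins, deviated by −0.71 and −0.60 there. Of 13 mitochondrial messenger RNAs 11 passed, with medians of −0.16 and −0.33 in the libraries numbered 2. Among poly(A)-selected libraries replicate 3, at 0.20, lay further from the mean for these RNAs. Of 11 fibroblast markers 8 passed, with medians of −0.23 and −0.20 in the libraries numbered 2. Firre deviated by −0.37 in the libraries numbered 2 (edgeR adjusted p = 5.58e-05), and the human X genes had 146 of 728 members past the threshold and a median of −0.13. Because replicate number is all that sets these libraries apart in the labels, no explanation was tested.

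In the patterns that follow, the scaling tests, the spread of Lars2 and its values under other settings, and the summing of mitochondrial copies were chosen after the result was seen. The first pattern is the lower level of ribosomal protein and nuclear oxidative phosphorylation genes in rRNA-depleted RNA. Short transcripts and expression level remain a possible explanation: 10000 lists of other protein-coding genes matched on effective length and mean CPM had median changes of −0.72 and −0.55 (central 95% −0.77 to −0.62 and −0.64 to −0.46), against −0.62 and −0.66 for the 84 and 77 members annotated as protein-coding. The match was incomplete, with a median log2 CPM of 7.04 for the matched lists against 7.91 for the ribosomal protein genes (5.45 against 5.75 for the other list) and a median log2 relative length of −1.43 against −1.62 (−1.80 against −1.94). The ribosomal protein list thus lay no lower than its matched lists, and the other list lay 0.015 beyond its interval, less than the 0.041 bootstrap SD of its median, so a decrease particular to these genes cannot be told apart from one shared by messenger RNAs of similar length and level. A test of scaling between the library types decides nothing: it set the full lists against all genes with library size alone (−0.66 and −0.68), a difference that a factor per library cannot alter. Scaling thus bears on the level against zero only, which was −0.41 and −0.44 with library size alone. No biological explanation was tested.

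Lars2, a mitochondrial leucyl-tRNA synthetase gene singled out after its values were seen, stood at −2.26 ± 0.715 (SE, edgeR adjusted p = 0.0211) in rRNA-depleted RNA. It stood at −3.80 without replicate 1 of the rRNA-depleted libraries (adjusted p = 6.96e-05) and −2.85 with the replicate block (adjusted p = 1.31e-07), and lost the call without replicate 1 of the poly(A)-selected libraries (−2.07, adjusted p = 0.0572). Its counts were 11394, 2301 and 1535 in the rRNA-depleted replicates 1 to 3, where Rn18s-rs5 had 109803, 18878 and 8996. A search of Lars2 transcripts for stretches of at least 50 bases at 90% identity to the annotated 18S and mitochondrial ribosomal RNAs found 0, but it decides nothing for the large cytoplasmic ribosomal RNA, which the annotation searched lacks (0 ribosomal RNA genes above 3000 bases). The SD of log2 Lars2 over Rn18s-rs5 was 0.227 of that of log2 Lars2 in rRNA-depleted and 0.47 in poly(A)-selected libraries, the latter above the bound set for the test. Over mt-Rnr2, the SD in poly(A)-selected libraries was 0.723, against 0.460 for Lars2 alone, so Lars2 did not follow that RNA there, and in rRNA-depleted libraries it was 0.595, against 1.61. Reads of cytoplasmic ribosomal RNA assigned to Lars2 may therefore contribute, and this stays open, as does a change of Lars2 itself.

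The decrease of mt-Co3 may mostly come from how reads are divided between it and a nuclear copy. In the poly(A)-selected libraries mt-Co3 held between 71.2% and 76.5% of the counts of the pair it forms with Gm28437, and in the rRNA-depleted libraries between 3.19% and 19.7%. Summed with the copy its log2 change was −1.221, against −3.76 alone, within the range of the other mitochondrial messenger RNAs (−2.31 to −0.23). In mt-Co2 and its copy Gm28661 on the same stretch of chromosome 1 the share moved the same way, from at least 92.4% to at most 62.0%, while mt-Atp6 moved from at most 98.3% to 100% of its pair with Atp6-ps. No biological explanation of the shift between copies was tested.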
